A study of Homo sapiens with 32 samples.

How the data were processed

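The 32 ribosome profiling libraries come from primary human platelets (1 resting, 2 with 0.01 U/ml thrombin for 60 min), primary reticulocytes (2 depleted with Ribo-Zero Gold, 2 with a globin RNA depletion), K562 erythroleukemia cells, and the megakaryoblastic line Meg01 with the platelet-like particles made from it. K562 cells were untreated (2 libraries), treated with 50 uM hemin (4 libraries), followed over days 0, 2, 4 and 6 of hemin with GFP or PH (8 libraries), or given an shRNA against ABCE1 or a control shRNA with GFP or PH (4 libraries). PH is read here as combined overexpression of the ribosome rescue factors PELO and HBS1L. Meg01 cells and particles gave 1 library each for GFP and PH (4 libraries). The untransfected set has 1 library each of cells, particles and particles labelled high salt.

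The labels name CASAVA 1.8, Bowtie2 2.2.6 and TopHat2 2.0.10 with the hg19 genome build, without stating which step each served; the read-length filter, the offset and the counting tool are not given in the sources used here. Per the file headers and the values, the authors' coding footprint columns hold whole-number counts of footprints in the coding sequence of 1 UCSC transcript. The deposited 3′ UTR score is a ratio, the density of footprints in the 3′ UTR over that in the coding sequence of the same transcript and library. Its product with the coding count was a whole multiple of 1 constant per transcript in 10023 of 10039 transcripts tested (99.8%, relative tolerance 1e-06), which allowed 3′ UTR reads to be recovered. The authors' particle ratio equalled the GFP score over the PH score in 4609 of 4609 transcripts, and their high-salt clearance ratio equalled high-salt over control 3′ UTR reads in 3864 of 3864. The deposited ABCE1 table holds counts of footprints by position from -100 to 100 and by read length, summed over transcripts. It holds positions and not genes, so the 2 gene tests designed for it (ABCE1 knockdown, and PH with shRNA) could not be fitted, and its position 0 is read as the stop codon from the shape of the profile. The labels give the hemin dose but not its duration for 4 K562 libraries; the column names give 2 and 10 days. Score columns of those libraries (4 columns of per-sample values) were not used. The deposited 3′ UTR scores after 2 and 10 days of hemin were therefore not examined here.

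Listing differs between the 7 tables. The hemin and the GFP and PH tables list a transcript in a library only where it has at least 1 coding and 1 3′ UTR footprint, the platelet table where it has at least 1 coding footprint, the reticulocyte table only 1312 transcripts seen in all 4 libraries, and the untransfected Meg01 table all coding transcripts. Listed coding footprints ranged from 349253 to 1297161 in platelets, 129469 to 1234723 in reticulocytes, 357679 to 4235705 in the hemin table, 169215 to 5261052 in the K562 GFP and PH table, 757401 to 6162138 in the Meg01 GFP and PH table and 656785 to 10038581 in the untransfected table. Shares carry exact 95% binomial (Clopper-Pearson) intervals, which cover counting error alone. Where a group has no reads, a fold is given against a floor of 3 counts over the group.

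Coding counts of transcripts listed in every library of a comparison were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F test, Benjamini-Hochberg adjusted p of 0.05). The standard error (SE) is the absolute log2 fold change over the square root of F. Models had thrombin, depletion method or hemin as the term. For the K562 time course they had construct with day as a factor, construct with day as a number (slope per day), or both with their product, and for Meg01 compartment with construct. Residual degrees of freedom were 1 in platelets and Meg01, 2 in reticulocytes, 4 for hemin, and 3, 5 and 4 for PH, day and their product in K562. In platelets the lone resting library is assumed to vary like the thrombin pair, and in Meg01 any interaction counts as spread. The platelet fit used a spread pooled over transcripts, not one for each transcript. Values called p measure the spread between libraries, which may be technical only, since the labels do not say what a replicate is. Scores were tested on the log2 scale with limma 3.58.1 in transcripts with a score in every library and a mean coding count of at least 100, with 0.01 added where scores of 0 are listed. Summaries per library were compared by exact permutation, and comparisons of 1 library with 1 were described as log2 ratios with no test. The particle ratios use transcripts with at least 100 counts and total-count scaling with 0.5 added to each count.

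The 22 gene lists, the comparisons, the tests, most alternatives and the naming rule were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), and in the untransfected particles set against 10000 random lists of transcripts with matched expression. Genes are named by a rule: PELO, HBS1L and ABCE1 in every library; the 10 largest changes each way past the adjusted p, with an average logCPM (log2 of footprints scaled to library size) of at least 5 and the same sign in every pair or groups that do not overlap; the 5 smallest p each way, as values, where none passed; up to 4 members of each list that passed or fitted the comparison; the 10 largest ratios each way where 1 library faces 1; and the 10 largest shares in each primary cell type. Other names are given as chosen after their values were seen.

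Alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts, the 10 most abundant transcripts left out, each library or day left out, the replicate number as a block, other count minimums (50 and 200 for scores, 30 and 300 for particles), a pseudocount of 0.1, TMM scaling of the particles, camera with an estimated correlation, and fry. Chosen after seeing the data were the comparison of 10 with 2 days of hemin, days 4 and 6 against days 0 and 2, unlisted transcripts taken as 0, edgeR on recovered 3′ UTR reads (sum of at least 10, coding count as offset), GFP libraries alone for the scores, the score minimum of 100, and ABCE1 footprints of 28 to 32 nt and of all lengths. The models were tested on simulated data with 200 changed transcripts. At 4-fold they recovered 46% in platelets, 100% in reticulocytes, 94% for hemin, 96% for PH and 76% for day in K562, 52% for particles and 38% for PH in Meg01, but 2% for the product of PH and day. For scores they recovered 34% for PH and 12% for day at 4-fold, and the product recovered 0% even at 64-fold. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. RNA sequencing was not used here.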

Results

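Hemin supplies K562 cells with heme and iron. With both durations pooled, the largest rises in coding footprints among the genes named by the rule were in the ferritin subunits that store iron. Over 4 hemin libraries (2 of 2 days, 2 of 10 days) against 2 untreated ones, FTL rose by a log2 fold change of 4.46 (SE 0.19, edgeR adjusted p = 0.00023) and FTH1 by 4.25 (SE 0.17, adjusted p = 0.000224). SLC7A11, a subunit of the cystine transporter, rose by 3.20 (SE 0.42), and the small Maf factors MAFF and MAFG by 2.91 (SE 0.34) and 2.53 (SE 0.32). Other rises were CEBPB by 2.58 (SE 0.33), PIM3 by 2.48 (SE 0.40), PPP1R18 by 2.42 (SE 0.32) and SNAI1 by 2.28 (SE 0.31). Falls were smaller. The RNA helicase DHX9 had a log2 fold change of -1.74 (SE 0.27), the splicing proteins HNRNPA1 and HNRNPM -1.11 (SE 0.15) and -1.01 (SE 0.13), and the cap-binding NCBP1 -1.05 (SE 0.16). The histones HIST1H3J, HIST1H1B and HIST1H1E stood at -1.47 (SE 0.13), -1.06 (SE 0.12) and -0.83 (SE 0.12), and IDI1, a cholesterol synthesis enzyme, fell as well. In all, 25 of 1698 transcripts rose and 12 fell (37 past the adjusted p, 413 at an unadjusted p under 0.05), while DESeq2 called 237. The group pools both durations, and few transcripts pass when 1 library is left out. There were 2 without untreated replicate 1, untreated replicate 2, or either 2 day library, 6 without 10 day replicate 1 and 4 without 10 day replicate 2.

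Of 16 gene lists with enough measured members, 8 moved against the other transcripts with both durations pooled (camera with its preset correlation), and none of the 8 passed with an estimated correlation. In the heme and oxidative response list 4 of 12 members rose (9 adjusted over the list alone; median log2 2.50, camera adjusted p = 6.15e-11). In the integrated stress response, the program that follows phosphorylation of eIF2, 2 of 10 rose (8 adjusted over the list alone; median 1.21, adjusted p = 4.86e-05). In the unfolded protein response 1 of 8, XBP1 at 1.42 (SE 0.25), rose (3 adjusted over the list alone; median 0.73, adjusted p = 0.00453). Cytosolic ribosomal proteins were lower (median -0.46, adjusted p = 3.85e-06), and 1 of 28 fell, RPS27 at -0.83 (SE 0.14; 12 adjusted over the list alone). DNA replication genes were lower too (median -0.72, adjusted p = 0.000436), and 1 of 7 fell, the sliding clamp PCNA at -0.86 (SE 0.13; 3 adjusted over the list alone). In oxidative phosphorylation (median -0.39, adjusted p = 4.09e-05) 1 of 26 fell, ATP5G3 at -0.70 (SE 0.11; 2 adjusted over the list alone). Of 11 replication histones 2 fell (4 adjusted over the list alone; median -0.35, adjusted p = 0.00037). Of 12 translation factors none passed (0 adjusted over the list alone), although the list was lower (median -0.34, adjusted p = 0.00984). The heme and oxidative response, the integrated stress response and DNA replication each had adjusted p = 0.0944 with an estimated correlation. The others had 0.112 for histones, 0.131 for oxidative phosphorylation, 0.153 for ribosomal proteins and 0.181 for the unfolded protein response and translation factors. Lists not called include heme synthesis (5 measured; adjusted p = 0.0831), erythroid genes (0 of 10; 1 adjusted over the list alone) and ribosome rescue factors (0 of 7; 1 adjusted over the list alone; adjusted p = 0.0831).

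After 2 days alone, when the pairs of libraries lie close together, many more transcripts passed than with both durations pooled. Between replicates, chi-square of the counts per degree of freedom was 1.44 at 2 days, 1.23 at 10 days and 3.28 untreated. Counting error alone gives about 1. The labels do not say whether replicates are separate cultures, so p at either duration may not cover the spread between cultures. HSPA1A, an inducible heat shock protein that shares reads with HSPA1B, rose by 4.47 on the log2 scale (SE 0.10, adjusted p = 8.68e-24; n = 2 and 2), FTH1 by 4.32 (SE 0.06), FTL by 4.31 (SE 0.06) and ATF3 by 3.77 (SE 0.20). The autophagy adaptor SQSTM1 rose by 3.44 (SE 0.07), GABARAPL1 by 3.14 (SE 0.20), the glutathione synthesis subunit GCLM by 3.06 (SE 0.07) and the co-chaperone DNAJB1 by 2.59 (SE 0.09). TFRC, the transferrin receptor that brings in iron, had the largest fall at -2.72 (SE 0.07, adjusted p = 1.25e-21). It was followed by SPN at -1.88 (SE 0.16), GALNT7 at -1.85 (SE 0.24) and LRRC61 at -1.64 (SE 0.27). Of 16 lists 10 were called at 2 days with the preset correlation, and none of them passed with an estimated one. All 12 of 12 members of the heme and oxidative response list rose (12 adjusted over the list alone; median 2.82, adjusted p = 2.36e-63, adjusted p = 0.0712 with an estimated correlation), among them TXNRD1 at 2.52 (SE 0.06). So did 10 of 10 of the integrated stress response (10 adjusted over the list alone; median 0.88, adjusted p = 4.52e-09). Proteasome subunits rose in 8 of 12 (9 adjusted over the list alone; median 0.46, adjusted p = 0.012), with PSMD14 at 0.75 (SE 0.07) and PSMB6 at 0.72 (SE 0.08). Members fell in 7 of 7 for DNA replication (RRM2 -0.99, SE 0.08, MCM4 -0.89, SE 0.07), 23 of 28 ribosomal proteins (RPL4 -0.49, SE 0.05, while 1 rose) and 20 of 26 of oxidative phosphorylation (2 rose). They also fell in 9 of 11 histones, 10 of 12 translation factors (EEF1A1 -0.41, SE 0.04), 6 of 9 cholesterol synthesis genes (CYP51A1 -0.96, SE 0.08) and 4 of 10 erythroid genes (RHAG -0.95, SE 0.06), of which 2 others rose (BNIP3L 0.50, SE 0.10). These 7 lists had adjusted p = 0.000184, 0.000151, 0.00191, 0.00115, 0.00914, 0.012 and 0.012 in that order. Their counts adjusted over the list alone were 7, 25, 22, 9, 11, 7 and 6. For these lists, the stress response and the proteasome adjusted p = 0.138 with an estimated correlation, save 0.224 for translation factors and 0.248 for histones. In heme synthesis 3 of 5 fell (among them UROD at -0.54, SE 0.06) and FECH, which inserts iron, rose by 0.38. That list was not called (adjusted p = 0.1; 4 adjusted over the list alone). Over all transcripts 507 rose and 498 fell (1005 of 1698; 780 by DESeq2).

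After 10 days the ferritins remained high (FTL 4.60, SE 0.07, adjusted p = 1.16e-27; FTH1 4.17, SE 0.07). The largest rise was in SH2B3, an adaptor that restrains cytokine signalling, at 5.28 (SE 0.20, adjusted p = 2.96e-18). Next came the kinase IRAK1 at 4.70 (SE 0.16), the DNA dioxygenase TET3 at 4.35 (SE 0.20), SLC25A23 at 4.31 (SE 0.24), AKNA at 4.20 (SE 0.26). Others were ST3GAL2 at 3.75 (SE 0.27), TCF3 at 3.71 (SE 0.14) and SKI at 3.70 (SE 0.21). The largest fall was that of NCL, the nucleolar protein nucleolin, at -2.44 (SE 0.09, adjusted p = 1.2e-18). It was followed by the chaperones HSPH1 and HSPA8 at -2.33 (SE 0.16) and -2.02 (SE 0.05), DDX52 at -2.26 (SE 0.29), DHX9 at -2.18 (SE 0.11) and the heterochromatin protein CBX3 at -2.13 (SE 0.14). In all 570 rose and 555 fell (1125 of 1698; 996 by DESeq2). At 10 days 6 lists were called with the preset correlation, and none of them passed with an estimated one. The heme and oxidative response rose in 10 of 12 (1 fell; 11 adjusted over the list alone; median 1.68, adjusted p = 1.53e-11), with SQSTM1 at 2.16 (SE 0.09) and GCLM at 1.42 (SE 0.10). The integrated stress response rose in 8 of 10 (1 fell; 9 adjusted over the list alone; median 1.28, adjusted p = 0.000225), with the amino acid transporter SLC7A5 at 3.56 (SE 0.12) and DDIT4 at 2.05 (SE 0.07). Ribosomal proteins fell in 23 of 28 (4 rose; 27 adjusted over the list alone; median -0.62, adjusted p = 7.54e-05) and oxidative phosphorylation in 19 of 26 (2 rose; 23 adjusted over the list alone; adjusted p = 0.00669). Histones fell in 8 of 11 (1 rose; 9 adjusted over the list alone; adjusted p = 0.0208) and DNA replication in 5 of 7 (5 adjusted over the list alone; adjusted p = 0.0428). For the heme list, ribosomal proteins and oxidative phosphorylation adjusted p = 0.208 with an estimated correlation, and it was 0.359 for the stress response, 0.377 for replication and 0.387 for histones. Mitotic genes fell in 4 of 7 (4 adjusted over the list alone; TPX2 -1.57, SE 0.12, TOP2A -1.24, SE 0.09). Proteasome subunits fell in 8 of 12 (1 rose; 9 adjusted over the list alone). Neither list was called (adjusted p = 0.0692 for each).

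**Figure D1:**
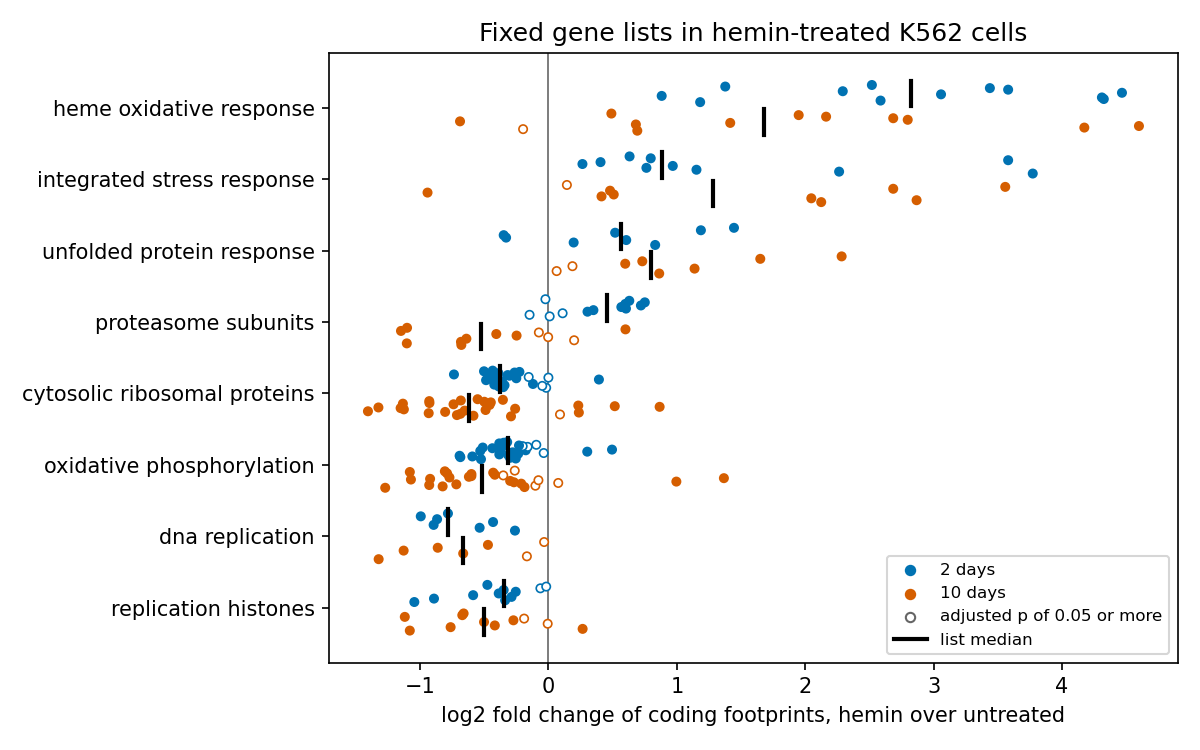
Log2 fold change of coding footprints after hemin (x axis) for the members of 8 gene lists (y axis) in K562, 2 days and 10 days against untreated, 2 libraries each. Filled points have an edgeR adjusted p under 0.05 and bars mark list medians, 2.82 and 1.68 for the heme and oxidative response.

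The 10 day libraries were also compared with the 2 day ones (2 with 2), a comparison chosen after seeing the data. HSPA1A had a log2 fold change of -5.15 (SE 0.18, adjusted p = 1.27e-18), HSPH1 -3.95 (SE 0.14), GABARAPL1 -2.96 (SE 0.37) and DNAJB1 -2.78 (SE 0.15). IRAK1 rose by 4.73 (SE 0.19) along with SLC25A23 (4.62), ST3GAL2 (4.38) and SH2B3 (4.19). Proteasome subunits fell in 10 of 12 (10 adjusted over the list alone; median -0.80, adjusted p = 0.000251, adjusted p = 0.384 with an estimated correlation). The heme and oxidative response fell in 9 of 12 (1 rose; 11 adjusted over the list alone; median -0.69, adjusted p = 3.73e-05, adjusted p = 0.409 with an estimated correlation). Erythroid genes rose in 7 of 10 and fell in 3 (10 adjusted over the list alone; median 0.86), without a call for the list (adjusted p = 0.573). In all 514 rose and 567 fell (1081 of 1698; 960 by DESeq2). Of the transcripts called at each duration against untreated, 225 rose at both and 276 fell at both (170.2 and 162.8 if the calls were independent). Both comparisons use the same untreated libraries, so the calls are not independent and the overlap is raised. The covariance of the log2 fold changes was 0.255, against 0.00553 in 1 set of counts simulated without change, in which 0 transcripts were called.

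The 8 libraries with GFP or PH give a separate hemin series, 1 library per construct and day. No transcript passed for the slope over days (edgeR: 0 of 1270, 255 at an unadjusted p under 0.05; DESeq2: 122, 74 up and 48 down). The genes with the smallest p are given as values. Slopes per day on the log2 scale, all with adjusted p = 0.0779, were 0.37 (SE 0.06) for the ribosomal protein RPL39 and 0.27 (SE 0.05) for the kinase PIM1. They were 0.39 (SE 0.07) for the p53 target BBC3, 0.40 (SE 0.08) for PRNP and 0.73 (SE 0.12) for ZNF99. On the lower side they were -0.36 (SE 0.06) for the glucocorticoid receptor co-chaperone FKBP5, -0.32 (SE 0.07) for the lamin B receptor LBR, -0.47 (SE 0.10) for HIST1H2BG, -0.30 for PDLIM5 and -0.30 for SLC38A5. None of 12 lists was called for the slope. Adjusted over the list alone, 3 of 18 cytosolic ribosomal proteins, 2 of 8 mitochondrial ribosomal proteins, 1 of 10 in the integrated stress response and 1 of 6 proteasome subunits passed. Across 811 transcripts tested in both series, the pooled hemin fold change and the slope had Pearson r = 0.447 (Spearman rho = 0.408). The 2 day fold change and day 2 over day 0 in GFP cells had r = 0.566. These are correlations across transcripts, which are not independent replicates. Leaving out day 6 gave 339 transcripts (157 up, 182 down), and days 2, 4 and 6 against day 0 gave 14 (12 up, 2 down).

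PELO, which splits stalled ribosomes, and its partner HBS1L, a GTPase, are the genes PH should raise. In the K562 series PELO was listed in PH cells on day 2 alone, with 1255 coding footprints (596 CPM, footprints scaled to the listed total). HBS1L had 262 and 167 CPM in PH cells on days 0 and 2, against 88.9 on day 2 and 148 on day 6 in GFP cells. ABCE1, which recycles ribosomes, stood at 404, 255, 267 and 320 CPM in GFP cells over the days and at 407 and 464 in PH cells on days 0 and 2. In the hemin table ABCE1 was at 615 and 597 CPM untreated and at 280 and 240 after 10 days. HBS1L stood at 240 untreated, 300 and 318 after 2 days and 159 and 162 after 10 days, and PELO at 87.8 untreated, 174 after 2 days and 61.5 after 10 days. A transcript missing from a library had no coding or no 3′ UTR footprint there, so the overexpression cannot be measured on the other days.

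Between PH and GFP within days, no coding transcript passed in K562 (edgeR: 0 of 1271, 11 at an unadjusted p under 0.05; DESeq2: 0, with 15 at an unadjusted p under 0.05; n = 4 and 4). The smallest p belonged to TNXB at 1.32 (SE 0.38), TOMM7, a mitochondrial import subunit, at 1.15 (SE 0.37), and PPA1 at 0.66 above GFP (adjusted p = 0.938). Below GFP it belonged to UBE2M at -0.62 (SE 0.22), BCL10 at -0.85 (SE 0.31) and WBP2 at -0.62, with the same adjusted p. Without day 6, 83 transcripts had an unadjusted p under 0.05. With camera, 6 of 12 lists differed, all with adjusted p = 0.561 with an estimated correlation. The integrated stress response (median -0.34, adjusted p = 0.00104) and the heme and oxidative response (-0.28, adjusted p = 0.0361) were lower with PH. Oxidative phosphorylation (0.40, adjusted p = 0.00104), histones (0.54, adjusted p = 0.00253), erythroid genes (0.30, adjusted p = 0.0361) and mitochondrial ribosomal proteins (0.22, adjusted p = 0.0491) were higher. No member of any list passed by itself, 0 adjusted over the list alone. For the product of PH and day edgeR called 0 of 1271 (38 at an unadjusted p under 0.05; DESeq2: 0). The smallest p belonged to SKP2 at 0.61 (SE 0.19), NDC1 at 0.35, SLC25A6 at -0.62 (SE 0.19) and TPM4 at -0.64 (SE 0.21) per day (adjusted p = 0.799). There 5 lists were called, each with adjusted p = 0.495 with an estimated correlation. Oxidative phosphorylation (0.16, adjusted p = 0.00271) and histones (0.24, adjusted p = 0.0272) went upward, and translation factors (-0.19, adjusted p = 0.00271), the contractile cytoskeleton (-0.24, adjusted p = 0.00432) and cytosolic ribosomal proteins (-0.13, adjusted p = 0.00528) downward. Again no member passed, 0 adjusted over the list alone.

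Footprints in 3′ UTRs can mark ribosomes that passed the stop codon without being recycled, and in K562 they were more frequent on days 4 and 6 of hemin. The median 3′ UTR score over 997 transcripts was 0.00526, 0.00571, 0.0506 and 0.0492 in GFP cells on days 0, 2, 4 and 6. It was 0.00456, 0.00668, 0.0705 and 0.0219 in PH cells, next to 0.00586 and 0.00696 in the untreated libraries of the hemin table. Days 4 and 6 averaged 0.0481 (SD 0.01995, n = 4) and days 0 and 2 averaged 0.00555 (SD 0.000889, n = 4; exact permutation p = 0.0286). That p is the smallest that 8 libraries allow, and the grouping was chosen after the values were seen. Slopes were positive for 576 of 997 transcripts past the adjusted p with limma and negative for none (674 at an unadjusted p under 0.05; edgeR on recovered reads, 672). The largest were KDELC2 at 1.29 per day (SE 0.22, adjusted p = 0.00283), the ATP synthase subunit ATP5G3 at 1.14 (SE 0.24), UHRF1BP1 at 1.13 and MORF4L2 at 1.12. They included the chaperone calnexin (CANX) at 1.12 (SE 0.24), the ferritin receptor NCOA4 at 1.10 (SE 0.23) and the monocarboxylate transporter SLC16A1 at 1.06. Members rose in 7 of 7 erythroid genes, 10 of 12 in the heme and oxidative response, 10 of 13 translation factors and 12 of 17 cytosolic ribosomal proteins. They rose in 7 of 12 cytoskeletal genes and 6 of 16 in oxidative phosphorylation, and no list differed from the other transcripts (lowest adjusted p = 0.37). The count rests on which days are included. There were 0 without day 0, 175 without day 2, 659 without day 4 and 653 without day 6, while 866 passed when days 4 and 6 were set against days 0 and 2 (864 up, 2 down) and 373 in GFP libraries alone. Depth also differs between libraries (PH on day 4 is the shallowest). The scores and slopes above were not thinned. A listed transcript has at least 1 3′ UTR read, so its lowest possible score is higher in a shallow library. Thinned to 169215 coding footprints the 3′ UTR reads per 100 coding footprints were 4.07, 3.40, 7.30 and 8.39 in GFP cells and 3.93, 3.61, 8.39 and 4.65 in PH cells. Unthinned, over the 997 transcripts, the gap was wider. The values were 1.11, 1.08, 5.91 and 5.82 in GFP cells and 1.04, 1.16, 7.51 and 3.18 in PH cells.

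**Figure D2:**
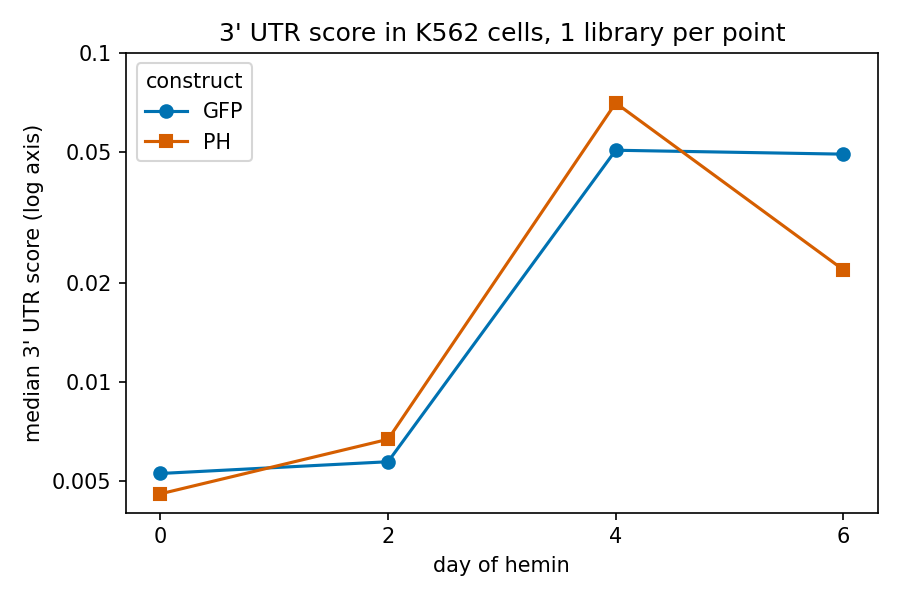
Median 3′ UTR score of 997 transcripts (y axis, log scale) against days of hemin (x axis) in K562 with GFP or PH, 1 library per point. Scores lie between 0.00456 and 0.00668 on days 0 and 2 and between 0.0219 and 0.0705 on days 4 and 6.

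PH and GFP cells did not differ detectably in these scores. The median log2 ratio of PH to GFP was -0.14, 0.15, 0.52 and -1.21 on days 0, 2, 4 and 6 (PH lower in 801 of 997 transcripts on day 6, 1 library each). The median scores gave exact permutation p = 0.875 (smallest possible 0.125, n = 4 pairs). By transcript, limma called 0 of 997 for PH (32 at an unadjusted p under 0.05). The smallest p were those of PTER at 1.94 (SE 0.63) and ABI1 at 1.66, and of the coat protein COPZ1 at -1.86 (SE 0.57) and the nucleoporin NUP210 at -1.97 (SE 0.63), all with adjusted p = 0.999. The product of PH and day gave 0 of 997 as well (0 at an unadjusted p under 0.05), in a test that recovered no simulated change. CLTC at 0.85 (SE 0.49) and MDK at -0.94 (SE 0.49) had the smallest p. None of 11 lists was called for either.

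With an shRNA against ABCE1, the factor that splits terminated ribosomes, a larger share of footprints lay around and beyond the stop codon. In footprints of 28 to 34 nt, positions 0 to 100 held 6.24% (95% interval 5.75 to 6.76) in GFP cells with shABCE1 against 1.61% (1.47 to 1.76) with the control shRNA, and 3.51% (3.10 to 3.96) against 1.78% (1.67 to 1.90) in PH cells. Positions -12 to -1 held 3.60% against 0.488% in GFP cells and 1.16% against 0.547% in PH cells. The peak at position -16 stood at 9.17 times the coding mean in GFP cells with shABCE1, against 1.93, 2.15 and 2.17 in GFP control, PH control and PH shABCE1. The libraries differ in length, since footprints of 33 and 34 nt made up 33.8% and 32.2% of these in the GFP and PH controls but 0.111% and 0.318% with shABCE1. At 28 to 32 nt, a range chosen after seeing the data, the peak stood at 9.18 and 2.18 in GFP and PH cells with shABCE1 against 1.26 and 1.46 in the controls. Positions 0 to 100 then held 6.25% and 3.52% against 1.55% and 1.72%. The libraries also differ in reading-frame signal. At 28 to 34 nt the largest frame held 35.9% and 37.5% of coding footprints in GFP and PH cells with shABCE1. It held 44.8% and 42.9% in the GFP and PH controls. With shABCE1 the footprints were thus close to an even split over the reading frames. Length and frame signal differ along with the shRNA, so these profiles cannot separate the knockdown from other differences between the libraries. At positions 0 to 100 the order of PH and GFP under shABCE1 depends on read length. Over all lengths these positions held 8.71% in GFP and 11.3% in PH cells with shABCE1, against 2.50% and 2.68% in the controls. The peak at position -16 over all lengths stood at 8.30 and 1.90 with shABCE1, against 1.91 and 2.15 in the controls. PH cells with shABCE1 thus lay below their control in that setting. Each condition is 1 library (9023 and 7242 footprints with shABCE1, 30741 and 48833 in the GFP and PH controls), so replicates cannot be compared. The table holds no gene counts from which ABCE1 itself could be measured.

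**Figure D3:**
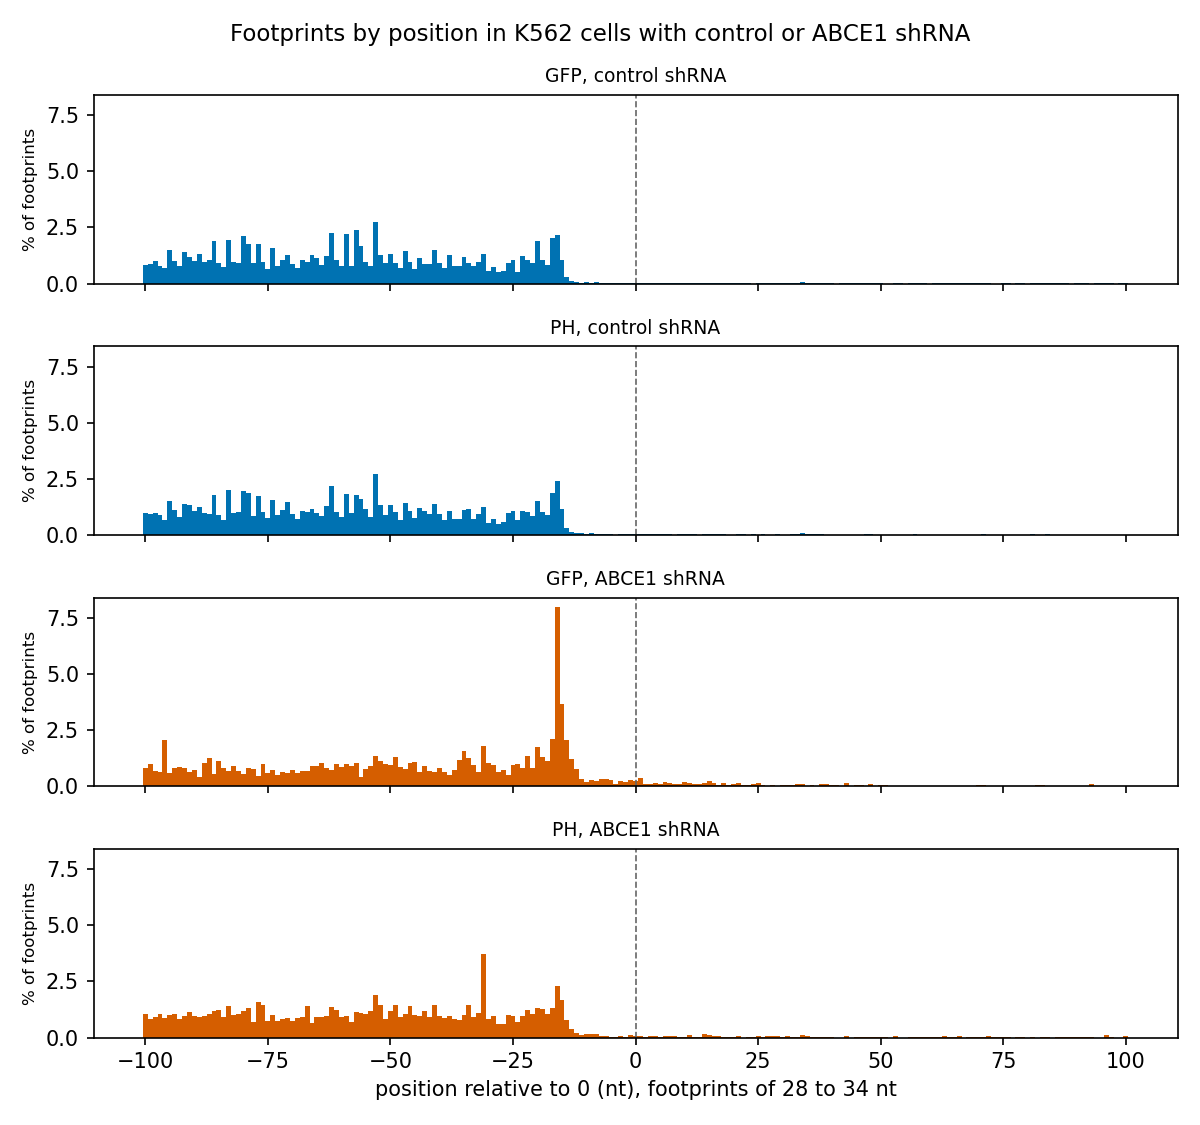
Percent of footprints of 28 to 34 nt (y axis) at each position from -100 to 100 (x axis) in K562 with GFP or PH and a control or ABCE1 shRNA, 1 library each. Position -16 holds 8% in GFP cells with shABCE1, against 2.32% in PH cells with shABCE1 and 2.15% and 2.39% in the GFP and PH controls.

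In particles shed by Meg01 cells, 3′ UTR footprints were far fewer with PH than with GFP. The median score over 1522 transcripts was 0.243 in GFP particles and 0.0140 in PH particles, or 21.0 and 1.40 3′ UTR reads per 100 coding footprints. The median log2 ratio was -4.06 (quartiles -5.10 and -2.87), with a lower score in 1495 of 1522 transcripts. Scores of GFP and PH particles were 0.272 and 0.00327 for the tubulin TUBA1B, 0.640 and 0.00784 for HSP90AB1 and 0.165 and 0.00510 for beta-actin (ACTB). The elongation factors EEF2 and EEF1A1 had 0.738 and 0.0335, and 0.0902 and 0.00430. FTL was higher with PH (0.459 and 0.547). These genes have many footprints and were chosen after their values were seen. PH was lower in 62 of 62 cytosolic ribosomal proteins (median log2 -3.07), 22 of 22 cytoskeletal genes (-4.88) and 27 of 27 translation factors (-4.16). It was also lower in 12 of 12 rescue factors (-4.61), 30 of 30 in oxidative phosphorylation (-2.56), 5 of 5 platelet genes (-0.95) and 10 of 11 in the heme and oxidative response. This is 1 library against 1, so no p is given and replicates cannot be compared. HBS1L stood at 132 CPM in GFP particles, 421 in PH particles and 195 in PH cells. ABCE1 stood at 409 and 372 CPM in GFP and PH cells and at 193 and 572 in GFP and PH particles, and PELO was not listed in any of the 4.

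**Figure D4:**
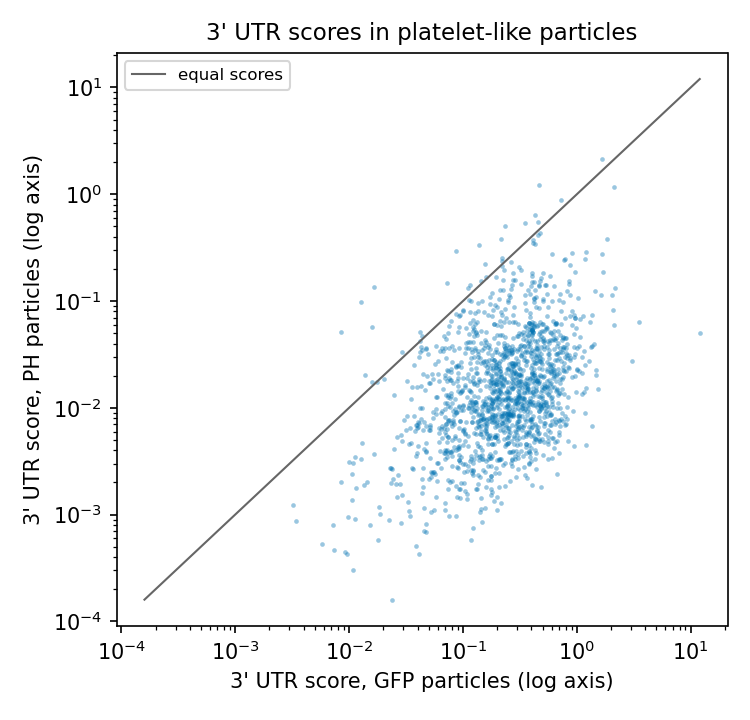
3′ UTR score of each of 1522 transcripts in platelet-like particles with GFP (x axis) and PH (y axis), log scales, 1 library each, with the line of equality. The score is lower with PH in 1495 transcripts, and the medians are 0.243 and 0.0140.

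Coding footprints of the same 4 Meg01 libraries gave no transcript past the threshold for particles against cells (edgeR: 0 of 2776, 229 at an unadjusted p under 0.05; DESeq2: 30, 8 up and 22 down). The smallest p belonged to IRGQ at 5.28 (SE 0.85), DVL1, of Wnt signalling, at 3.64 (SE 0.85), NPIPL3 at 3.09 and the chromatin remodeler CHD2 at 1.76, higher in particles (adjusted p = 0.587). Lower in particles were RCN2 at -2.20 (SE 0.47), SYNGR2 at -2.36 (SE 0.51), the iron exporter SLC40A1 at -2.20 (SE 0.49), LY6E at -2.51 and CD99 at -2.46, with the same adjusted p. Changes over 2-fold numbered 1128 of 2827 in the GFP pair (509 higher, 619 lower) and 386 in the PH pair (62 higher, 324 lower). Of these, 36 were higher and 140 lower in both (11.2 and 70.9 if independent). Camera placed translation factors (median 0.55, adjusted p = 0.0287) and DNA replication (0.71, adjusted p = 0.036) higher in particles. Neither held (adjusted p = 0.877 with an estimated correlation), and no member passed, 0 adjusted over the list alone. Between PH and GFP edgeR called 0 of 2776 (15 at an unadjusted p under 0.05; DESeq2: 0, with 63 at an unadjusted p under 0.05). NCL at 1.52 (SE 0.52), DDX6 at 1.15 (SE 0.44), FBXW7 at -2.23 (SE 0.74), HSP90B2P at -1.72 and ATP5I at -1.25 (SE 0.48) had the smallest p (adjusted p = 0.917). Cholesterol synthesis (median -0.78, adjusted p = 0.01) and the heme and oxidative response (-0.98, adjusted p = 0.01; FTH1 -2.69, SE 1.23, and FTL -2.13, SE 1.19) were lower with PH. The contractile cytoskeleton (0.40, adjusted p = 0.0164) was higher. All 3 had adjusted p = 0.864 with an estimated correlation and 0 members adjusted over the list alone.

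In untransfected particles, immediate early genes were higher than in the Meg01 cells they came from, and ribosomal and mitochondrial genes lower. Of 14 immediate early genes, 13 were higher (median log2 ratio 1.32, percentile 100 among random lists), against a median of -0.16 over 9414 transcripts. FOS stood at 4.39, JUN at 3.28, FOSB at 3.06, EGR1 at 2.89, DUSP1 at 2.14 and JUNB at 2.03. All 54 of 54 mitochondrial ribosomal proteins (median -1.12, with MRPL33 at -2.40), 44 of 49 oxidative phosphorylation genes (-1.10, COX7A2 -2.14) and 68 of 75 cytosolic ribosomal proteins (-0.71, RPL41 -2.56) were lower, each at percentile 0. So were 17 of 17 histones (-0.83, HIST1H4C -1.55, percentile 0.32) and 6 of 6 globins (-1.34, HBA1 -1.57, HBG1 -0.76, percentile 0.13). Rescue and recycling factors were higher in 17 of 27 (median 0.51, percentile 99.96), led by the ATPase VCP at 3.65, the decay factor UPF1 at 2.68 and the release factor GSPT1 at 2.04. DENR (-1.81), MCTS1 (-1.28), HBS1L (-0.52) and ABCE1 (-0.41) lay lower. Platelet and megakaryocyte genes divided 10 higher and 13 lower (median -0.01, percentile 78.2, with ITGA2B at -0.18 and TMSB4X at -2.04). The p53 targets (4 of 13 higher, median -0.26, percentile 36.3) and heme synthesis (3 of 9 higher, percentile 45.5) lay within the random range. Among the largest ratios were NKX2-3 at 10.92 (2642 footprints against 9), FEZF2 at 7.67 (190 against 6) and members of the NPIP family, which share reads. GDF7 had 130 footprints in particles and 0 in cells, and C6orf223 had 128 and 2. Among the smallest were the mitotic SKA1 at -3.02, MZT1 at -2.83, LYRM7 at -2.69 and DNAJC19 at -2.69. These are ratios of 1 library to 1, without a p or replicates to compare. The random lists were matched on expression and not on coding length. The percentiles therefore cannot tell the function of a list from the length of its members. In the GFP and PH table the immediate early list had the opposite direction (median -0.56, not called; JUN 0.95, SE 0.54, JUNB -2.01, SE 1.04). Across 2643 transcripts the ratios in the GFP and PH table and in the untransfected one had Pearson r = 0.295 (rho = 0.262). This is a correlation across transcripts, which are not independent replicates.

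High salt, which the label names without saying how it was applied, went with fewer 3′ UTR footprints in particles. The median score over 2256 transcripts was 0.0464 in control and 0.00767 after high salt (6.88 and 2.93 reads per 100 coding footprints). It was lower in 1650 transcripts and higher in 416, with a median log2 ratio of -0.89. The high-salt library is shallower (656785 against 1444732 coding footprints). Scores of 0 made up 43.75% of these transcripts with high salt and 9.40% in control, which lowers the high-salt median. These 2 libraries were not thinned to equal depth. In coding footprints, 9 of 10 immediate early genes (median log2 -1.14, percentile 0), 16 of 16 histones (-0.76, percentile 0) and 69 of 75 cytosolic ribosomal proteins (-0.44, percentile 0) were lower after high salt. So were 9 of 14 in the heme and oxidative response (-0.42, percentile 0.16). Unfolded protein response genes were higher in 13 of 14 (0.43, percentile 99.8) and mitotic genes in 10 of 14 (0.36, percentile 99.3). The mitotic list lay within the random range at minimums of 30 counts (0.12, percentile 86.8) and 300 counts (0.16, percentile 79.9). By transcript, NKX2-3 was at -2.84 and DENND4B at -3.28, and IRS2 had 109 footprints in control and 0 after high salt. GOLGA4 at 1.56, SIGLEC9 at 1.52 and CASC5 at 1.45 were the highest. Each side is 1 library with no replicate, and here too the random lists were not matched on coding length. PELO, HBS1L and ABCE1 stood at 33.6, 89.95 and 294 CPM in cells, 49.1, 62.3 and 221 in control particles and 47.2, 71.6 and 230 after high salt.

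Platelets hold no nucleus and translate the messages their megakaryocyte left, and the 10 most abundant transcripts took 28.04% of coding footprints at rest and 25.7% and 25.4% with thrombin. Beta-2 microglobulin (B2M) took 5.87% of listed coding footprints at rest (95% interval 5.82 to 5.91) and 10.7% and 10.3% with thrombin. In the same order, the actin-binding peptide TMSB4X took 3.57%, 2.94% and 3.10%, the chemokine precursor PPBP 3.67%, 2.08% and 2.11%, and ferritin FTH1 2.32%, 2.27% and 2.29%. Platelet factor 4 (PF4) took 0.795%, 1.66% and 1.61% and the ferritin receptor NCOA4 0.588%, 1.27% and 1.27%. The GTPase RAP1B took 1.13%, 1.31% and 1.24%, RGS18 1.29%, 1.17% and 1.16%, and SDPR 1.03%, 1.06% and 1.02%. PHKG2 took 7.53% of the resting library and was listed in neither thrombin library. PELO, HBS1L and ABCE1 had 5, 23 and 73 coding footprints at rest and 1, 5 and 8 or 7, 6 and 25 with thrombin.

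With thrombin (2 libraries) against rest (1 library), the chemokine PF4 rose by 0.93 on the log2 scale (SE 0.10) and PF4V1, which shares reads with it, by 1.12 (SE 0.11), whereas PPBP had -0.91 (SE 0.07) and CCL5 -0.51 (SE 0.14). Rises were largest in UQCR11, of respiratory complex III, at 2.35 (SE 0.33, edgeR adjusted p = 2.81e-10), DNAJC9 at 2.05 (SE 0.58) and SUMO3 at 1.90 (SE 0.49). They included the platelet gene SH3BGRL2 at 1.33 (SE 0.21, adjusted p = 7.78e-08), the nuclear transport factor NUTF2 at 1.32 (SE 0.31), WRB at 1.30 (SE 0.41), PDZK1IP1 at 1.29 (SE 0.41) and TREML1, a platelet surface receptor, at 1.28 (SE 0.30). DDX11L9, a pseudogene whose family shares reads, stood at 1.56 (SE 0.26). Falls were far larger, with RTTN at -6.99 (SE 0.38, adjusted p = 4.16e-71) and NFXL1 at -6.30 (SE 0.20). NAV2 went from 1159 footprints at rest to 2 and 1 with thrombin, a log2 ratio of -8.19 by counts alone (95% interval -10.47 to -6.63) and -8.20 in the model (SE 0.46, adjusted p = 2.66e-64). Others were the mechanosensitive channels PIEZO2 and PIEZO1 at -6.27 (SE 0.45) and -4.38 (SE 0.72), PLXNB3 at -4.99 (SE 0.60), POLE at -4.73 (SE 0.76), HMMR at -4.63 (SE 0.36), DEGS1 at -4.38 (SE 0.58) and GEN1 at -4.08 (SE 0.75). In all, 84 of 4339 transcripts rose and 69 fell (153 in all, 475 at an unadjusted p under 0.05). DESeq2 called 99, and edgeR 270 (91 up, 179 down) with unlisted transcripts taken as 0. The spread comes from the thrombin pair alone, and the resting library has no replicate. In this fit each transcript took a spread pooled over the tested transcripts in place of its own. The very small p values lean on that pooling and not on how closely the thrombin libraries agree for each transcript.

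Platelet and megakaryocyte genes rose in 8 of 34 and fell in 2 (13 adjusted over the list alone; median 0.28, camera adjusted p = 0.000794, adjusted p = 0.853 with an estimated correlation), with NRGN at 1.27 (SE 0.17) and SPARC at 1.06 (SE 0.15). Of 14 mitotic genes HMMR alone fell (1 adjusted over the list alone; median -0.36, adjusted p = 0.00537, adjusted p = 0.853 with an estimated correlation). Among the 14 lists not called, 3 of 25 cytoskeletal genes rose (5 adjusted over the list alone; adjusted p = 0.12). They were MYL6 at 1.10 (SE 0.20), PFN1 at 1.00 (SE 0.25) and TUBA4A at 0.60 (SE 0.19). HEMGN fell among 14 erythroid genes (-0.92, SE 0.21; 3 adjusted over the list alone), and SLC40A1 rose among 10 of the heme and oxidative response (0.90, SE 0.28). CCL5 fell among 5 leukocyte markers, DNAJC3 fell among 10 of the unfolded protein response (-0.93, SE 0.22), and NEMF, of the ribosome quality control complex, fell among 13 rescue factors (-1.34, SE 0.25; list median -0.70, adjusted p = 0.144).

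Platelets carried many 3′ UTR footprints in every state. There were 59.3 reads per 100 coding footprints at rest and 52.5 and 54.9 with thrombin, with median scores of 0.0737, 0.0541 and 0.0638. Scores rose with thrombin for 9 and fell for 118 of 1067 transcripts (limma, 127), but 114 of the 118 had scores of 0 in both thrombin libraries. There the thrombin values are equal, so both the call and the size of the fall depend on the pseudocount. These 114 shared an SE of 0.019, and their resting 3′ UTR reads ran from 1 (GP9, HERC1) to 86 (TRIP11). The 3′ UTR score of ACTB was 0.266 at rest and 0.543 and 0.557 with thrombin (log2 change 1.02, SE 0.03, adjusted p = 0.048). That of the phosphatase PTPN12 was 0.105, 0.270 and 0.280 (1.31, SE 0.04). The kinase STK39 had a score of 0 at rest and 0.0312 and 0.0313 with thrombin (adjusted p = 0.0166). Scores rose for SIAE by 1.63 (SE 0.05), TLK1 by 1.15, the carnitine palmitoyltransferase CPT1A by 1.06 (SE 0.02) and DAZAP2 by 0.78. At rest and in the 2 thrombin libraries, recovered 3′ UTR reads were 2, 5 and 9 for SIAE and 21, 9 and 24 for CPT1A. They were 0, 5 and 10 for STK39, but 1241, 686 and 1326 for ACTB. Each SE rests on how closely the 2 thrombin scores agree, so with few reads it can understate counting error. POTEE and POTEJ (1.70) rose too and share reads with ACTB. MCUR1, of the mitochondrial calcium uniporter, fell from a score of 6.81 to 0.175 and 0.168 (log2 change -5.23, SE 0.05, adjusted p = 0.0166). Against a floor of 3 reads over the thrombin pair, scores were at least 12.4-fold lower for the centrosomal CEP350, 10.9-fold for TRIP11, 6.01-fold for the methyltransferase KMT2A, 5.39-fold for BIRC6 and 2.92-fold for TRIP12, a ubiquitin ligase. With 1 residual degree of freedom and scores of 0 in the thinner thrombin libraries, the count moves with the setting. It was 281 and 34 at coding minimums of 50 and 200, 50 with a pseudocount of 0.1 and 37 (13 up, 24 down) with edgeR on recovered reads.

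Globins filled the reticulocyte libraries, and globin RNA depletion removed HBB and HBD more than HBA1 and HBA2. HBB took 49.3% and 48.7% of coding footprints with Ribo-Zero Gold and 12.7% and 12.6% after globin depletion, and HBD 9.16% and 8.85% against 3.52% and 3.03%. HBA1 took 18.4% and 18.7% against 19.9% and 18.6%, and HBA2, which shares reads with HBA1, 18.3% and 18.7% against 20.1% and 18.5%. All globins together held 95.2% and 95.1% against 56.6% and 53.1%. Against the other transcripts, 6 of 9 globins fell (6 adjusted over the list alone; median -3.18, camera adjusted p = 2.14e-150, adjusted p = 0.0684 with an estimated correlation). They were HBZ at -6.09 (SE 0.31, edgeR adjusted p = 6.31e-15; 292 footprints in the Ribo-Zero Gold pair and 5 in the depleted pair), HBB at -5.20 (SE 0.21), HBD at -4.70 (SE 0.18), HBA1 at -3.19 (SE 0.18), HBA2 at -3.18 (SE 0.18) and HBG1 at -2.07 (SE 0.12). These 6 were the only ones past the threshold among 1263 transcripts with edgeR (128 at an unadjusted p under 0.05), and none of the other 14 lists was called. By counts alone, scaled to the listed totals that globins fill, HBZ had a log2 ratio of -2.90. Its 95% interval of -4.54 to -1.66 is wide beside the SE of 0.31. Leaving out Ribo-Zero Gold replicate 2 gave 14, and 2 passed once the 10 most abundant transcripts were left out. With globins reduced, other messages took larger shares. The interferon-inducible IFI27 took 0.216% and 0.224% against 2.06% and 2.14%, and B2M 0.0835% and 0.0822% against 0.905% and 1.14%. The mitophagy receptor BNIP3L took 0.0716% and 0.0723% against 0.779% and 0.872%, and IGHG1 0.0877% and 0.0794% against 0.675% and 0.677%. ACTB took 0.0753% and 0.0835% against 0.606% and 0.676%, and ALAS2, the erythroid enzyme that starts heme synthesis, 0.0675% and 0.0588% against 0.599% and 0.670%. Counts outside globins were 58798 and 46823 with Ribo-Zero Gold and 56138 and 70768 with globin depletion. For 3′ UTR scores limma called 0 of 119 transcripts (9 at an unadjusted p under 0.05; edgeR on recovered reads, 5, of which 3 up and 2 down). HBA1 at -1.48 (SE 0.21, adjusted p = 0.349) and HBG1 had the smallest p, and the median scores were 0.0550, 0.04997, 0.0549 and 0.0543. PELO, HBS1L and ABCE1 were not listed in reticulocytes.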

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

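All tests in this part of the 3 patterns below, and the comparison of 10 with 2 days of hemin, were chosen only after the results were seen. In K562, 197 transcripts were called in opposite directions at 2 and 10 days of hemin against untreated, 99 higher and then lower and 98 lower and then higher. Independent calls would give more (165.7 and 167.2), although the shared untreated libraries make the calls dependent. All 197 passed a test of 10 against 2 days as well, which their selection makes all but certain. Among them HSPA1A (-5.15) and HSPH1 (-3.95) had lower log2 values at 10 days than at 2, and FADS1 (2.79), SPN (2.36), ABHD2 (2.05) and CARD9 (2.78) higher ones. In the ABCE1 profiles 25.1% of footprints in GFP cells and 28.02% in PH cells with shABCE1 lay outside 28 to 34 nt, a range the main comparison does not use, against 9.82% and 10.7% in the controls. In the resting platelet library 10.8% of coding footprints (139837 in 5744 transcripts) belonged to transcripts listed in no thrombin library, led by PHKG2 with 97670. Dixon's test on 21 sets of 4 hemin values, which pool both durations, set no library apart; with 4 values it says little about stability.

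The higher 3′ UTR scores on days 4 and 6 of hemin in K562 could follow from depth, from listing only transcripts with a 3′ UTR read, or from a few transcripts. A few transcripts are argued against for GFP on day 6, which scored above the shallower PH library of day 2 in 956 of 997 transcripts. Over all libraries 98.1% of transcripts had a higher mean score on days 4 and 6. That share decides little, since the lowest score a listed transcript can have is higher in the shallow late libraries. Listing is argued against too: with unlisted transcripts of a fixed set at 0, the lowest late median was 1.51 times the highest early one. Depth as the whole cause is argued against for GFP on days 4 and 6 and PH on day 4: with every library thinned to the shallowest, the lowest of these was 1.796 times the highest early value in 3′ UTR reads per 100 coding footprints. GFP on day 6 is also deeper than PH on day 2 (3213508 and 2105353 footprints), yet its scores had a median ratio of 7.27 to those of PH on day 2. Depth stays open for PH on day 6, which after thinning was only 1.14 times the highest early value. Chance stays open too: of 34 splits of the 8 libraries into 4 and 4, 1 (the real one) called as many transcripts (866, highest other 0), but this grouping was chosen because it separates the scores, so the count decides nothing. Hemin exposure itself remains untested here as a cause, and the deposited replicate scores after 2 and 10 days of hemin were not used.

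The lower 3′ UTR scores with PH than GFP in platelet-like particles may reflect depth, a difference between single libraries, or PH. Depth is argued against, because with PH particles thinned to the 757401 coding footprints of GFP particles, 3′ UTR reads per 100 coding footprints were 25.4 and 2.89 in GFP and PH, an 8.79-fold difference. A difference between single libraries stays open: GFP particles and untransfected particles, both without PH, differed 2.43-fold (21.5 and 8.87 reads per 100 over 1688 shared transcripts, against 1.41 with PH). An effect of PH on 3′ UTR ribosomes in particles is a hypothesis that 1 library each leaves untested.

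Resting platelet transcripts with few or no thrombin footprints, such as NAV2 and PHKG2, could come from depth, from reads of another origin, or from thrombin. Depth is argued against, since 92.1% of transcripts with like resting counts were listed in both thrombin libraries. Reads of another origin assigned to the coding sequence alone are a candidate explanation: the 55 transcripts tested had a median resting 3′ UTR score of 0.00479 against 0.0783 in 1551 others (permutation p = 2e-05, the smallest the permutations can give). An effect of thrombin remains open and untested, with 1 resting library.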

How the results depend on the processing

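Of the summary results under all alternatives, 112 stayed within 1.5 times or within their interval, 33 moved and 1 reversed; of the values for named genes, 2715 kept their direction and side of the threshold, 227 lost the threshold and none reversed. The reversal is in the ABCE1 profiles: PH minus GFP with shABCE1 at positions 0 to 100 was -2.73 percentage points at 28 to 34 nt and 2.57 over all lengths (at -12 to -1, -2.44 and -2.08), a setting chosen after seeing the data. With the DESeq2 test counts went from 153 to 99 in platelets, 37 to 237 for hemin, 0 to 122 for the day slope and 0 to 30 for particles. Leaving out 1 library or day gave 6 to 14 in reticulocytes, 2 to 6 for hemin, 0 to 339 for the day slope and 0 to 659 (0 without day 0, 175 without day 2) for slopes of 3′ UTR scores. Each duration of hemin alone gave 1005 (2 days) and 1125 (10 days), with a smaller spread within durations than in the pooled group. Hemin days 2, 4 and 6 against day 0 gave 14. Leaving out the 10 most abundant transcripts gave 2 in reticulocytes, most globins being removed by construction. Pairs taken alone gave 1128 (GFP) and 386 (PH) particle changes over 2-fold, without a test. Settings chosen after seeing the data gave 270 platelet transcripts with unlisted ones as 0, and for 3′ UTR scores 866 (days 4 and 6 against days 0 and 2) and 373 (GFP alone) in K562, 37 in platelets and 5 in reticulocytes with edgeR on recovered reads. Platelet scores gave 281, 34 and 50 at coding minimums of 50 and 200 and a pseudocount of 0.1. The 27 list calls of the designed models became 0 with an estimated correlation and 12 with fry, which asks a different question; the 10, 6 and 2 calls at 2 days, at 10 days and between these became 0 and 14, 15 and 9. Agreement of the particle ratios went from r = 0.295 to 0.244 at 300 counts or more, across transcripts. Of the particle lists, 7 (of 20 at 100 counts) lay outside the central range of random lists; 6 did under every minimum and scaling, globins being too few at 300 counts. Libraries with the same replicate number showed no shared deviation (correlations of deviations 0.00126, 0.0392 and -0.0140 for hemin and -0.0427 for reticulocytes). This does not settle whether the samples were paired, which the labels do not say. A replicate block gave 2 for hemin and 9 for reticulocytes. The cause was not tested unless given. The gene tests designed for the ABCE1 table, and their alternatives, were not run.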

Other observations

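Further transcripts were called in opposite directions at 2 and 10 days of hemin against untreated. The tests of other splits of the libraries were chosen only after the results were seen. The chaperone HSP90AB1 had log2 fold changes of 0.29 and -1.53 against untreated, and HSP90AA1 0.32 and -1.46. INSIG1 went the other way, with -0.74 and 1.63. The proteasome subunit PSMD14 had 0.75 and -1.15, the peroxidase PRDX1 0.74 and -0.46, fetal globin HBG1 0.83 and -0.67, the poly(A)-binding protein PABPC1 -0.93 and 0.85, and the formin DIAPH1 -0.39 and 2.32. These genes were chosen after their values were seen, and they stand for no tested group.

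Whether the split into PH and GFP libraries gives more calls in K562 than other splits of the same 8 libraries was tested for each model. Where the real split calls none, every split gives as many, so the count decides nothing. This holds for PH, in 32 of 32 splits for coding transcripts (0, highest other 0) and 32 of 32 for 3′ UTR scores (0, highest other 0). It holds for the product of PH and day, in 35 of 35 for coding transcripts (0, highest other 279) and 35 of 35 for scores (0, highest other 434). For the product, every split with calls divided the days unevenly between its sides, and splits even over days gave no calls. Uneven splits mix the product with day, so their counts are no measure of chance for PH. For the lists, 10 of 32 splits gave as many as PH (6, highest other 7) and 13 of 35 as many as the product (5, highest other 7), so chance cannot be excluded for these list calls.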
